A study of Arabidopsis thaliana with 12 samples.

How the data were processed

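RNA was sequenced from Arabidopsis thaliana seedlings 2 to 3 weeks old, infiltrated under vacuum and collected 6 h later, with leaf given as the tissue. Per the labels' protocols, RNA was extracted with an RNeasy Plant Mini kit and libraries were made with the CORALL total RNA-seq kit. The 12 libraries form 4 groups of 3: mock, valinomycin, the bacterium Pseudomonas syringae pv. tomato DC3000 (here DC3000), and both together. Valinomycin, an antibiotic that carries potassium ions across membranes, was given at 10 µM. The genome build was TAIR10 per the submitters' processing notes. The aligner, the quantifier and the use of read strand are not given in the sources used here.

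The deposited table holds 1 value per gene and library for 20233 genes, normalized by the authors. No unit is stated, and FPKM (fragments per kilobase of transcript and per M (mega) fragments) was inferred from the deposited values, because the library totals, 1057472 to 1350272, differ and lie above the total of a table in transcripts per M. In 6 of the 12 libraries low values multiplied by transcript length also fell on regular steps, more so than with 95 or more of 100 permutations of the lengths. These 6 are mock replicates 1 and 3, DC3000 replicate 3 and all 3 libraries given both treatments. Their steps of 0.0759 to 0.085 FPKM times kilobase correspond to 11.8 to 13.2 M (mega) fragments. At that depth 1 FPKM is 20.2 to 22.6 fragments on a median transcript of 1.72 kb. The depth of the other 6 libraries is unknown, and no counts were used. No value in the table is 0, so genes with a 0 in any library, and others without a value, were not analysed here.

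Values were transformed as log2(FPKM + 1), and genes with a mean of at least 1 FPKM over the 12 libraries were tested, which left 18048. A fold change on this scale understates the change of genes with low values. All 12 libraries entered 1 linear model of group means with 8 residual degrees of freedom in limma 3.58.1 under R 4.3.3, with empirical Bayes moderation and a trend of the spread with expression. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. The comparisons were each treatment against mock, both treatments against each single one, and the interaction, which is the valinomycin effect with DC3000 minus that without. The tests, the threshold, the 25 gene lists, the rule for naming genes and most of the other settings tested were chosen before the data were examined.

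Gene lists were tested with camera, limma's test of a list against all other genes, with a preset correlation of 0.01 between genes and adjustment over the 25 lists. Each was run again with a correlation estimated per list. The lists cover salicylic acid and systemic resistance, jasmonate, ethylene, pattern-triggered immunity, camalexin and indolic defence compounds, aliphatic glucosinolates, mitochondrial stress, potassium transport, heat shock, endoplasmic reticulum stress, abscisic acid and water deficit, hypoxia, low energy, calcium sensing, xenobiotic detoxification, photosynthesis, flavonoids, phenylpropanoids and lignin, auxin response, cell division and the circadian clock. A further 4 lists hold markers of guard cells, roots, phloem and xylem, and shoot meristem and epidermis. Counts of called members were made over all genes and adjusted over the list alone.

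Genes were named by rule. In valinomycin against mock, DC3000 against mock and both against DC3000 these were the 8 largest rises and 8 largest falls among called genes whose groups of libraries do not overlap, which chance gives to 10% of genes at 3 against 3, and whose higher mean is at least 8.70 FPKM, the median over tested genes. The other comparisons gave the 3 largest each way, without the overlap condition for the interaction. Each list gave up to 4 called members with the largest change, or 2 members as values where fewer than 2 were called. A fixed set of marker genes was added. This gave 259 genes, of which the text names a part. Coordinates are those of TAIR10.1, in which all 20054 nuclear loci of the table were found by locus tag. Transcripts of the named genes were searched with blastn 2.17.0 for copies of at least 95% identity over at least 50% of their length, and exon overlaps were taken with bedtools 2.31.1. A copy was found for 7 named genes, an exon overlap on the same strand for 6 and on the opposite strand for 56.

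Tested on simulated data with the spread of these libraries, the model recovered 81% of genes with a log2 change of 1 in valinomycin against mock, 82% in DC3000 against mock, 83% in both against mock, 87% in both against DC3000 and 81% in both against valinomycin. At a log2 change of 2 it recovered 99%, 98%, 98%, 100% and 99% in the same order, with 13, 5, 15, 19 and 7 false calls. A simulated shifted list had a camera adjusted p of 9.97e-45 and 0 other lists were called. Genes were simulated independently of each other, so these simulations do not test camera on correlated genes. In the real libraries the estimated correlation ran from 0.147 for auxin response to 0.683 for mitochondrial stress. Other settings tested changed the pseudocount, the filter on low values, the scaling, the libraries in the fit, the list test, and the libraries included, or added the replicate number as a replicate block. Numbers in the labels were tested for pairing across groups: in 18 pairs of libraries the correlation of residuals ran from -0.242 to 0.439, 3 exceeded 0.1, and 5 were the best match of their number, so the groups were not paired. Scaling nuclear genes to 1 total was added after seeing the data. A model of counts was not run, since the values are FPKM. No 2 libraries of the 66 pairs shared more than 1 equal value among all genes. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.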

Results

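The data collected were FPKM values of 20233 genes in 12 libraries, 3 for each of the groups mock, valinomycin, DC3000 and both treatments. Library totals ran from 1057472 to 1350272 FPKM. The depth could be read from the values in 6 libraries, at 11.8 to 13.2 M (mega) fragments, and is unknown in the other 6. Chloroplast genes made up 41.9% ± 0.926 of the values in mock (mean ± SD, n = 3, as for all group values below), 36.5% ± 3.297 with valinomycin, 37.8% ± 2.85 with DC3000 and 35.1% ± 3.47 with both. The 2 ribosomal RNA loci made up 12.2% ± 3.00, 11.02% ± 1.36, 15.97% ± 4.71 and 16.6% ± 0.992 in the same order. Nothing in the labels says that the libraries came from separate plants or cultures, so the p-values measure only the spread between these samples. Differences are log2 fold changes ± their standard errors, and adjusted p-values of single genes come from limma.

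The groups separated in the first 2 principal components, which held 57.3% and 25.2% of the variance. Mock stood apart from all treated libraries on the first. Valinomycin replicate 3 lay nearer to mock than replicates 1 and 2: its changes from mock had a slope of 0.626 on the effect of both treatments, against 0.855 and 0.830.

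**Figure D1:**
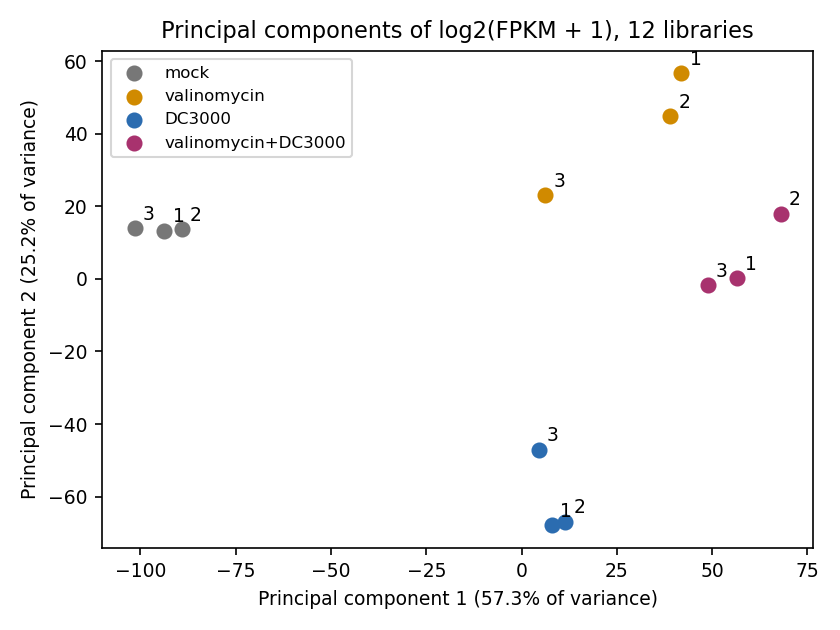
Principal components 1 (57.3% of the variance) and 2 (25.2%) of log2(FPKM + 1), 1 point per library, coloured by group and numbered by replicate. The mock libraries stand at the left, and valinomycin replicate 3 lies nearer to mock than the other valinomycin libraries.

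All 12 tested genes of the circadian clock list were called against mock in each of the 3 treated groups, 7 higher and 5 lower (12 in each group adjusted over the list alone). LHY (AT1G01060; chromosome 1, 33365 to 37871, minus strand), a morning-phased transcription factor of the clock, stood at 266 ± 52.9 FPKM in mock, 9.13 ± 7.23 with valinomycin, 1.305 ± 0.699 with DC3000 and 2.83 ± 1.05 with both. GI, an evening-phased clock gene, stood at 0.312 ± 0.0671, 21.4 ± 2.48, 17.3 ± 2.02 and 16.7 ± 1.61 FPKM. The median absolute change of the clock genes was 3.16 with valinomycin and 3.31 with DC3000 on the log2 scale, but 0.26 between both treatments and DC3000 and 0.28 between both treatments and valinomycin. The clock difference therefore accompanies every comparison with mock below and the interaction. Between treated groups some clock genes still differed. With both treatments CCA1, RVE8 and PRR9 were called higher than with DC3000 alone. LHY and CCA1 fell by 1.199 and 0.92 on the log2 scale against valinomycin alone (limma adjusted p = 0.0462 and 0.0471). These 2 calls rest on single libraries (limma adjusted p up to 0.147 for LHY without valinomycin+DC3000 replicate 3 and 0.144 for CCA1 without valinomycin replicate 1) and were lost after rescaling (limma adjusted p = 0.0836 and 0.0919). Members moved both ways, and camera did not call the clock list against mock for valinomycin (camera adjusted p = 0.295, and adjusted p = 0.723 with an estimated correlation). For DC3000 the test gave camera adjusted p = 0.438, and adjusted p = 0.865 with an estimated correlation. For both it gave camera adjusted p = 0.248, and adjusted p = 0.703 with an estimated correlation.

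Valinomycin against mock asks what the potassium carrier alone did to the transcriptome. Genes of mitochondrial stress and of the detoxification of foreign compounds were among the largest rises. CYP81D8 (AT4G37370; chromosome 4, 17569740 to 17571743, minus strand), a cytochrome P450, rose from 2.64 ± 0.737 to 507 ± 334 FPKM (log2 fold change 6.86 ± 0.50, limma adjusted p = 1.02e-07). The next largest rises by the naming rule were in 4 genes of none of the lists, AT2G41730 at 6.81 ± 0.38, AT4G08555 at 6.50 ± 0.54, AT5G24640 at 6.47 ± 0.46 and AT2G18193 at 6.33 ± 0.39 (limma adjusted p = 8.41e-09, 3.79e-07, 7.41e-08 and 1.96e-08). AOX1A (AT3G22370; chromosome 3, 7906521 to 7908746, plus strand), the alternative oxidase of the mitochondrial respiratory chain, rose from 4.37 ± 0.722 to 249.8 ± 125 FPKM (log2 fold change 5.400 ± 0.32, limma adjusted p = 1.59e-08). UPOX, induced by oxidative stress, rose by 5.97 ± 0.27 (limma adjusted p = 1.26e-09) and the glucosyltransferase gene UGT74E2 by 6.30 ± 0.42 (limma adjusted p = 4.27e-08). The efflux carrier gene DTX3 rose by 6.06 ± 0.36 (limma adjusted p = 1.48e-08) and the glutathione S-transferase gene GSTF6 by 6.02 ± 0.40 (limma adjusted p = 4.63e-08). In mitochondrial stress 17 of 18 tested members were higher and 1 lower (the same adjusted over the list alone). The median of these members stood 3.66 above that of all genes (camera adjusted p = 4.78e-07, and adjusted p = 0.377 with an estimated correlation). In xenobiotic detoxification 26 of 27 tested members were higher and 0 lower (the same adjusted over the list alone). Xenobiotic detoxification stood 3.34 above it (camera adjusted p = 3.5e-10, and adjusted p = 0.377 with an estimated correlation). The median of all genes was itself 0.27, and the value at which a list is said to stand is its median relative to that of all genes, here and below.

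Defence genes rose with valinomycin alone. WRKY40 and WRKY33 encode transcription factors induced in immunity. WRKY40 rose from 2.08 ± 0.765 to 169 ± 94.8 FPKM (log2 fold change 5.63 ± 0.37, limma adjusted p = 4.04e-08). WRKY33 rose from 7.15 ± 2.15 to 246 ± 154 FPKM (log2 fold change 4.72 ± 0.49, limma adjusted p = 2.94e-06). FRK1, a receptor kinase gene induced by bacterial flagellin, stood at 0.0554 ± 0.0257 in mock and 5.91 ± 2.97 FPKM with valinomycin (log2 fold change 2.63 ± 0.28, limma adjusted p = 3.72e-06). PAD3, which makes the last step to camalexin, rose from 0.210 ± 0.0628 to 20.7 ± 7.47 FPKM (log2 fold change 4.09 ± 0.29, limma adjusted p = 7.04e-08). In pattern-triggered immunity 25 of 29 tested members were higher and 0 lower (the same adjusted over the list alone). Pattern-triggered immunity stood at 2.25 (camera adjusted p = 2.38e-08, and adjusted p = 0.377 with an estimated correlation). In camalexin and indolic compounds 13 of 16 tested members were higher and 1 lower (the same adjusted over the list alone). Camalexin and indolic compounds stood at 1.24 (camera adjusted p = 0.000138, and adjusted p = 0.377 with an estimated correlation). In jasmonate synthesis and response 24 of 26 tested members were higher and 0 lower (the same adjusted over the list alone). Jasmonate synthesis and response stood at 1.52 (camera adjusted p = 1.89e-07, and adjusted p = 0.377 with an estimated correlation). The synthesis gene AOC2 rose from 2.15 ± 0.565 to 46.8 ± 2.597 FPKM (log2 fold change 3.94 ± 0.18, limma adjusted p = 1.26e-09). The repressor gene JAZ1 rose from 5.64 ± 1.11 to 66.2 ± 28.3 FPKM (log2 fold change 3.26 ± 0.27, limma adjusted p = 3.78e-07). VSP2, a storage protein gene induced by jasmonate, was at 2.58 ± 0.526 and 3.88 ± 1.61 FPKM and was not called (limma adjusted p = 0.3). In ethylene synthesis and response 16 of 20 tested members were higher and 1 lower (the same adjusted over the list alone). Ethylene synthesis and response stood at 1.38 (camera adjusted p = 2.8e-05, and adjusted p = 0.377 with an estimated correlation). ACS2, an enzyme of ethylene synthesis, rose by 3.22 ± 0.38 (limma adjusted p = 9e-06). In salicylic acid and systemic resistance 8 of 18 tested members were higher and 3 lower (9 and 3 adjusted over the list alone). Salicylic acid and systemic resistance was not called (camera adjusted p = 0.374, and adjusted p = 0.757 with an estimated correlation). Of its 27 genes 20 have values, and the markers PR1, ALD1 and FMO1 were not analysed here, so its result covers a part of the pathway.

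Other stress lists were called higher as well. The small heat shock protein gene HSP17.6A rose from 1.17 ± 0.493 to 109 ± 41.7 FPKM (log2 fold change 5.61 ± 0.28, limma adjusted p = 2.89e-09). The chaperone gene HSP90-1 rose from 12.6 ± 1.07 to 185 ± 71.7 FPKM (log2 fold change 3.70 ± 0.28, limma adjusted p = 1.53e-07). In heat shock 15 of 19 tested members were higher and 0 lower (the same adjusted over the list alone). Heat shock stood at 2.11 (camera adjusted p = 1.66e-05, and adjusted p = 0.432 with an estimated correlation). DIN1, induced by darkness, rose from 21.8 ± 4.53 to 526 ± 155 FPKM (log2 fold change 4.50 ± 0.33, limma adjusted p = 1.19e-07). In the low energy list 15 of 17 tested members were higher and 0 lower (the same adjusted over the list alone). The low energy list stood at 1.28 (camera adjusted p = 5.87e-06, and adjusted p = 0.377 with an estimated correlation). In hypoxia 9 of 10 tested members were higher and 0 lower (the same adjusted over the list alone). Hypoxia stood at 1.33 (camera adjusted p = 0.000111, and adjusted p = 0.377 with an estimated correlation). The fermentation gene PDC2 rose from 0.820 ± 0.172 to 34.6 ± 4.92 FPKM (log2 fold change 4.29 ± 0.16, limma adjusted p = 1.43e-10). In calcium sensing 9 of 12 tested members were higher and 1 lower (10 and 1 adjusted over the list alone). Calcium sensing stood at 1.55 (camera adjusted p = 0.00509, and adjusted p = 0.525 with an estimated correlation). The calmodulin-like gene CML37 rose from 0.295 ± 0.0199 to 39.0 ± 16.6 FPKM (log2 fold change 4.84 ± 0.49, limma adjusted p = 2.18e-06). In potassium transport 15 of 32 tested members were higher and 5 lower (16 and 6 adjusted over the list alone). Potassium transport was not called (camera adjusted p = 0.618, and adjusted p = 0.913 with an estimated correlation), and its root uptake gene HAK5 was not analysed here. KUP9, a potassium transporter gene, rose from 3.79 ± 0.942 to 13.3 ± 3.63 FPKM (log2 fold change 1.57 ± 0.21, limma adjusted p = 2.65e-05). In abscisic acid and water deficit 14 of 26 tested members were higher and 0 lower (the same adjusted over the list alone). Abscisic acid and water deficit was not called (camera adjusted p = 0.23, and adjusted p = 0.757 with an estimated correlation). In endoplasmic reticulum stress 9 of 20 tested members were higher and 0 lower (7 and 0 adjusted over the list alone). Endoplasmic reticulum stress was not called (camera adjusted p = 0.275, and adjusted p = 0.723 with an estimated correlation).

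Lists of photosynthesis, pigment synthesis and growth were called lower. LHCB2.3, a light-harvesting protein gene, fell from 903 ± 51.6 to 203 ± 57.7 FPKM (log2 fold change -2.18 ± 0.20, limma adjusted p = 9.33e-07). In photosynthesis 29 of 48 tested members were lower and 1 higher (30 and 1 adjusted over the list alone). Photosynthesis stood at -0.77 (camera adjusted p = 3.94e-13, and adjusted p = 0.377 with an estimated correlation). F3H, an enzyme of flavonoid synthesis, fell from 17.85 ± 2.44 to 2.55 ± 0.479 FPKM (log2 fold change -2.41 ± 0.18, limma adjusted p = 1.53e-07). In flavonoids and anthocyanins 6 of 8 tested members were lower and 0 higher (the same adjusted over the list alone). Flavonoids and anthocyanins stood at -1.58 (camera adjusted p = 6.24e-06, and adjusted p = 0.377 with an estimated correlation). KNOLLE, needed for cytokinesis, fell from 41.8 ± 9.51 to 14.0 ± 5.02 FPKM (log2 fold change -1.55 ± 0.24, limma adjusted p = 0.000124). In cell division 11 of 14 tested members were lower and 0 higher (the same adjusted over the list alone). Cell division stood at -1.16 (camera adjusted p = 5.16e-07, and adjusted p = 0.377 with an estimated correlation). In aliphatic glucosinolates 1 of 14 tested members were lower and 0 higher (the same adjusted over the list alone, and 9 lower and 0 higher after rescaling). Aliphatic glucosinolates stood at -0.65 (camera adjusted p = 0.00628, and adjusted p = 0.533 with an estimated correlation), and fry did not call it (adjusted p = 0.294). LHY, BMY3 and COL2 were among the largest falls. BMY3, a beta-amylase family gene, fell from 142 ± 7.14 to 7.70 ± 3.46 FPKM (log2 fold change -4.11 ± 0.23, limma adjusted p = 1.07e-08). COL2, related to the flowering regulator CONSTANS, fell from 134 ± 22.1 to 4.74 ± 0.463 FPKM (log2 fold change -4.55 ± 0.16, limma adjusted p = 6.41e-11). In auxin response 6 of 14 tested members were higher and 6 lower (the same adjusted over the list alone). Auxin response was not called (camera adjusted p = 0.15, and adjusted p = 0.533 with an estimated correlation). In phenylpropanoids and lignin 4 of 15 tested members were higher and 3 lower (3 and 3 adjusted over the list alone). Phenylpropanoids and lignin was not called (camera adjusted p = 0.0664, and adjusted p = 0.601 with an estimated correlation), but was called lower with a replicate block (camera adjusted p = 0.046). Among markers of other cell types, 2 of 6 genes of guard cells were higher and 1 of 5 of roots, 2 of 9 of phloem and xylem and 2 of 6 of meristem and epidermis were lower, against 1, 1, 2 and 2 adjusted over the list alone, and none of these lists was called (camera adjusted p = 0.998, 0.454, 0.119 and 0.155).

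In total 9436 genes were called, 6943 higher and 2493 lower, and 3400 of these changed at least 2-fold, 2628 higher and 772 lower. After rescaling to median-of-ratios size factors, which ran from 0.742 in mock replicate 3 to 1.14 in valinomycin replicate 2, 9683 genes were called with 4808 higher and 4875 lower. This rescaling sets the median change near 0 (0.01, against 0.27 before), which by itself evens the directions, here and below. With nuclear genes scaled to 1 total, a setting chosen after seeing the data, 6371 were higher and 3213 lower. Camera called 14 of the 25 lists, 10 higher and 4 lower, and with an estimated correlation 0 lists, the lowest adjusted p being 0.377. With fry, limma's test of whether a list moves at all, 18 were called.

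**Figure D2:**
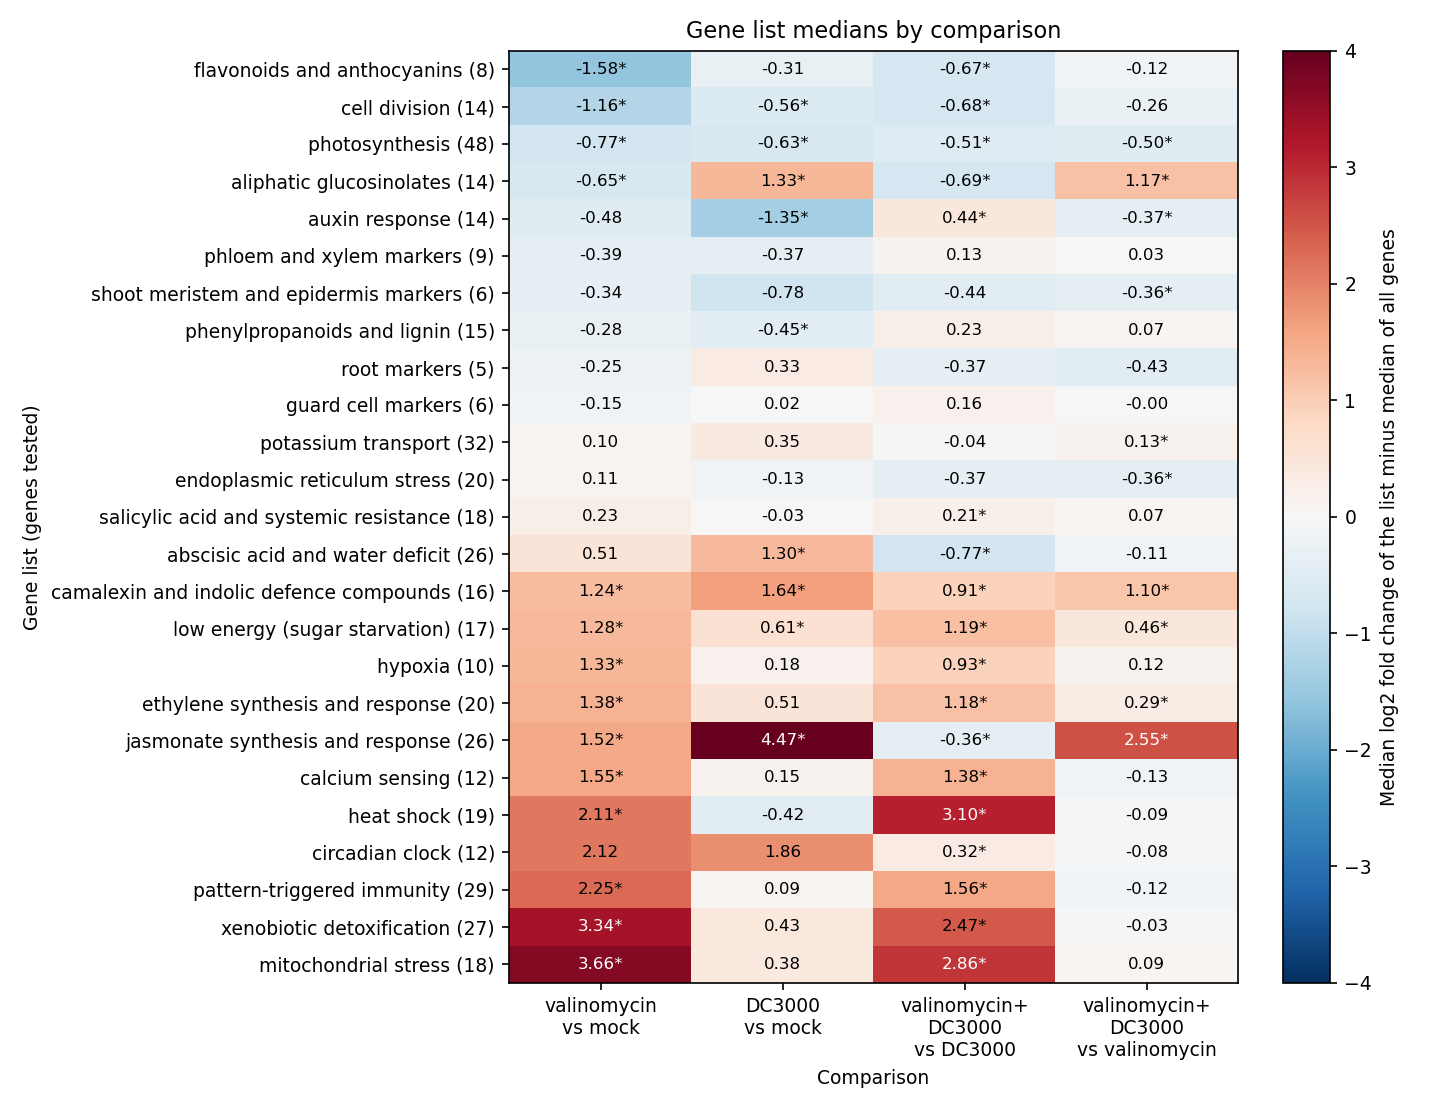
Median log2 fold change of each of the 25 gene lists minus the median of all genes, by comparison, with the number of genes tested in brackets. An asterisk marks a camera adjusted p under 0.05 with the preset correlation, and none of these holds with an estimated correlation. Mitochondrial stress stands at 3.66 in valinomycin against mock and jasmonate at 4.47 in DC3000 against mock.

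DC3000 against mock asks what the bacterium alone did. Genes of jasmonate synthesis and response were among the largest rises. AOC2 (AT3G25770; chromosome 3, 9406669 to 9408071, plus strand) rose from 2.15 ± 0.565 to 551 ± 129 FPKM (log2 fold change 7.44 ± 0.18, limma adjusted p = 3.81e-12) and VSP2 (AT5G24770; chromosome 5, 8500468 to 8502224, minus strand) from 2.58 ± 0.526 to 416 ± 165 FPKM (log2 fold change 6.78 ± 0.31, limma adjusted p = 6.38e-10). JAZ10, a repressor of the pathway, rose from 1.47 ± 0.315 to 232 ± 81.0 FPKM (log2 fold change 6.50 ± 0.28, limma adjusted p = 3.18e-10). In this list 26 of 26 tested members were higher and 0 lower (the same adjusted over the list alone). This list stood at 4.47 above the median of all genes, which was 0.18 (camera adjusted p = 1.08e-20, and adjusted p = 0.414 with an estimated correlation). NATA1, an N-acetyltransferase gene, stood at 0.251 ± 0.164 in mock and 162 ± 30.3 FPKM with DC3000 (log2 fold change 7.02 ± 0.20, limma adjusted p = 1.32e-11). AT1G53903 and AT1G53885, near-identical copies whose values are uncertain, rose by 6.84 ± 0.27 and 6.71 ± 0.23 (limma adjusted p = 1.73e-10 and 4.07e-11).

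Abscisic acid, glucosinolate and indolic defence genes rose too. RD26 and RD20 respond to desiccation. RD26 rose from 10.5 ± 3.47 to 207 ± 62.9 FPKM (log2 fold change 4.16 ± 0.27, limma adjusted p = 1.97e-08). RD20 rose from 19.8 ± 8.68 to 393 ± 129 FPKM (log2 fold change 4.27 ± 0.35, limma adjusted p = 2.35e-07). COR15B, a cold-regulated gene, rose by 4.22 ± 0.36 (limma adjusted p = 2.73e-07). In abscisic acid and water deficit 19 of 26 tested members were higher and 0 lower (the same adjusted over the list alone). Abscisic acid and water deficit stood at 1.301 (camera adjusted p = 0.00036, and adjusted p = 0.645 with an estimated correlation). MAM1, an enzyme of methionine chain elongation, rose from 21.4 ± 5.23 to 102 ± 16.4 FPKM (log2 fold change 2.22 ± 0.27, limma adjusted p = 1.01e-05). In aliphatic glucosinolates 12 of 14 tested members were higher and 0 lower (the same adjusted over the list alone). Aliphatic glucosinolates stood at 1.33 (camera adjusted p = 0.000727, and adjusted p = 0.645 with an estimated correlation). GGP1, of glucosinolate and camalexin synthesis, rose from 30.9 ± 5.96 to 338 ± 102 FPKM (log2 fold change 3.38 ± 0.23, limma adjusted p = 3.44e-08). The tryptophan synthesis gene ASA1 rose from 7.35 ± 0.358 to 57.0 ± 8.32 FPKM (log2 fold change 2.79 ± 0.16, limma adjusted p = 7.49e-09). In camalexin and indolic compounds 10 of 16 tested members were higher and 1 lower (the same adjusted over the list alone). Camalexin and indolic compounds stood at 1.64 (camera adjusted p = 0.00296, and adjusted p = 0.645 with an estimated correlation). PAD3 was at 0.210 ± 0.0628 and 0.892 ± 0.275 FPKM and was not called (limma adjusted p = 0.0794). Its libraries did not overlap, at up to 0.282 FPKM in mock and 0.722 or more with DC3000. FRK1 likewise stood at up to 0.0789 FPKM in mock and 0.505 or more with DC3000. At such low values the log2 scale used here understates a change. In the low energy list 11 of 17 tested members were higher and 0 lower (12 and 0 adjusted over the list alone). The low energy list stood at 0.61 (camera adjusted p = 0.00573, and adjusted p = 0.645 with an estimated correlation).

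In pattern-triggered immunity 7 of 29 tested members were higher and 4 lower (the same adjusted over the list alone). Pattern-triggered immunity was not called (camera adjusted p = 0.922, and adjusted p = 0.973 with an estimated correlation). WRKY40 rose from 2.08 ± 0.765 to 104 ± 39.5 FPKM (log2 fold change 5.04 ± 0.37, limma adjusted p = 6.73e-08). WRKY18, a related factor, rose by 1.47 ± 0.35 (limma adjusted p = 0.00312). In mitochondrial stress 8 of 18 tested members were higher and 2 lower (the same adjusted over the list alone). Mitochondrial stress was not called (camera adjusted p = 0.438, and adjusted p = 0.973 with an estimated correlation). AOX1A rose from 4.37 ± 0.722 to 14.4 ± 2.33 FPKM (log2 fold change 1.52 ± 0.32, limma adjusted p = 0.0013). In potassium transport 19 of 32 tested members were higher and 3 lower (the same adjusted over the list alone). Potassium transport was not called (camera adjusted p = 0.0638, and adjusted p = 0.863 with an estimated correlation), and after rescaling the list was called (camera adjusted p = 0.0275). KUP6, a potassium transporter gene, rose from 1.61 ± 0.545 to 17.2 ± 5.84 FPKM (log2 fold change 2.77 ± 0.23, limma adjusted p = 1.97e-07). TPK3, of the potassium channels, rose from 2.09 ± 0.376 to 11.5 ± 2.15 FPKM (log2 fold change 2.00 ± 0.18, limma adjusted p = 4.6e-07). Of heat shock genes, 4 were higher and 7 lower of 19 (5 and 7 adjusted over the list alone; camera adjusted p = 0.0694, and adjusted p = 0.863 with an estimated correlation). HSFA2, a heat shock transcription factor gene, fell from 13.9 ± 3.80 to 1.21 ± 1.03 FPKM (log2 fold change -2.82 ± 0.40, limma adjusted p = 4.18e-05). TCH4, a cell wall enzyme gene induced by touch, fell from 72.8 ± 15.8 to 7.53 ± 2.40 FPKM (log2 fold change -3.12 ± 0.38, limma adjusted p = 9.76e-06).

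The lists of photosynthesis, auxin, phenylpropanoids and cell division were called lower. RCA, which encodes Rubisco activase, fell from 3292 ± 240.5 to 1010.5 ± 18.3 FPKM (log2 fold change -1.70 ± 0.13, limma adjusted p = 8.77e-08). In photosynthesis 26 of 48 tested members were lower and 1 higher (29 and 2 adjusted over the list alone). Photosynthesis stood at -0.63 (camera adjusted p = 1.29e-10, and adjusted p = 0.645 with an estimated correlation). IAA3 and IAA19, repressors of auxin signalling, fell by 2.26 and 1.98 on the log2 scale (limma adjusted p = 2.36e-07 and 3.43e-05). In auxin response 8 of 14 tested members were lower and 1 higher (the same adjusted over the list alone). Auxin response stood at -1.35 (camera adjusted p = 0.00031, and adjusted p = 0.414 with an estimated correlation). CAD4, a lignin synthesis gene, fell from 56.2 ± 7.37 to 14.9 ± 1.19 FPKM (log2 fold change -1.84 ± 0.14, limma adjusted p = 7.13e-08). In phenylpropanoids and lignin 6 of 15 tested members were lower and 1 higher (7 and 1 adjusted over the list alone). Phenylpropanoids and lignin stood at -0.45 (camera adjusted p = 0.00879, and adjusted p = 0.645 with an estimated correlation). In cell division 6 of 14 tested members were lower and 0 higher (5 and 0 adjusted over the list alone). Cell division stood at -0.56 (camera adjusted p = 0.00573, and adjusted p = 0.645 with an estimated correlation), and fry did not call it (adjusted p = 0.0602). Cell type markers were, against mock, 0 lower and 0 higher of 6 for guard cells (0 and 0 adjusted over the list alone) and 1 lower and 2 higher of 5 for roots (1 and 3 adjusted over the list alone). They were 3 lower and 1 higher of 9 for phloem and xylem (3 and 1 adjusted over the list alone) and 3 lower and 1 higher of 6 for meristem and epidermis (3 and 1 adjusted over the list alone). None of these 4 lists was called (camera adjusted p = 0.922, 0.848, 0.0807 and 0.0694). CCA1, the partner of LHY, fell from 184 ± 32.9 to 3.85 ± 0.665 FPKM (log2 fold change -5.25 ± 0.29, limma adjusted p = 4.82e-09).

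In total 8803 genes were called, 5707 higher and 3096 lower, and 3261 changed at least 2-fold, 2116 higher and 1145 lower. After rescaling 9629 were called, 4694 higher and 4935 lower. Camera called 9 lists, 5 higher and 4 lower, and 0 with an estimated correlation, the lowest adjusted p being 0.414. Fry called 15.

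**Figure D3:**
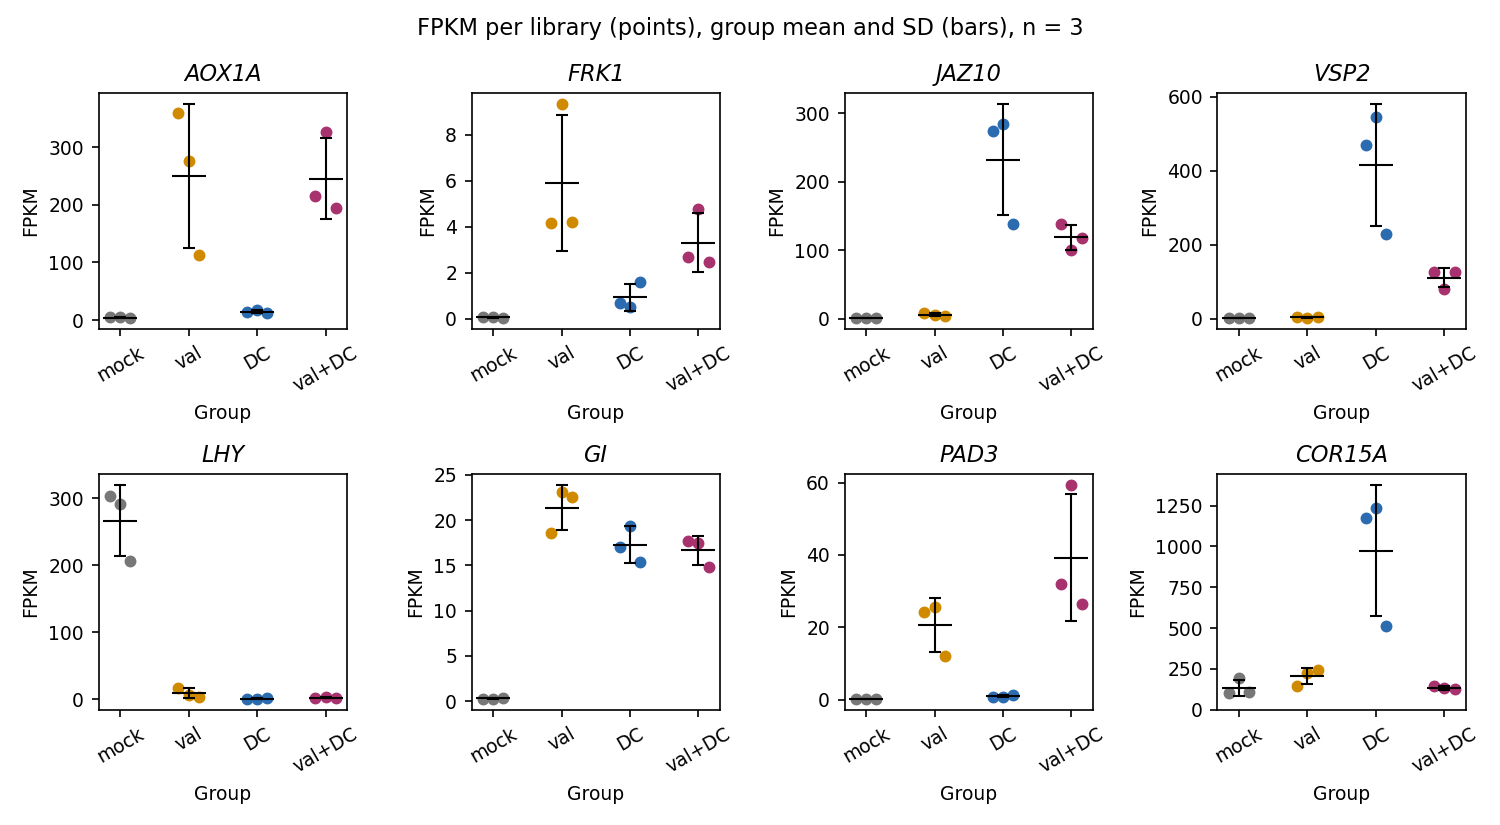
FPKM of 8 genes in each library (points) with the group mean and SD (bars, n = 3) for mock, valinomycin (val), DC3000 (DC) and both (val+DC). AOX1A is high with valinomycin with or without DC3000, VSP2 is lower with both treatments than with DC3000 alone, and LHY and GI separate mock from all treated groups.

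Both treatments against DC3000 alone asks what valinomycin changed in seedlings that also received the bacterium. Mitochondrial stress, detoxification, heat shock and immunity genes were again higher with valinomycin. UPOX rose from 7.31 ± 1.42 to 269.7 ± 27.2 FPKM (log2 fold change 5.03 ± 0.27, limma adjusted p = 1.72e-07) and HSP23.5, a mitochondrial small heat shock protein gene, from 2.35 ± 0.900 to 132 ± 47.6 FPKM (log2 fold change 5.29 ± 0.33, limma adjusted p = 3.52e-07). AOX1A rose from 14.4 ± 2.33 to 246 ± 71.0 FPKM (log2 fold change 3.97 ± 0.32, limma adjusted p = 3.25e-06). In mitochondrial stress 15 of 18 tested members were higher and 0 lower (17 and 0 adjusted over the list alone). Mitochondrial stress stood at 2.86 relative to all genes, whose median was -0.06 (camera adjusted p = 5.23e-16, and adjusted p = 0.207 with an estimated correlation). In xenobiotic detoxification 21 of 27 tested members were higher and 0 lower (22 and 0 adjusted over the list alone). Xenobiotic detoxification stood at 2.47 (camera adjusted p = 1e-15, and adjusted p = 0.207 with an estimated correlation). GSTU24, a glutathione S-transferase gene, rose from 4.61 ± 2.07 to 113 ± 39.1 FPKM (log2 fold change 4.35 ± 0.38, limma adjusted p = 4.68e-06). In heat shock 17 of 19 tested members were higher and 0 lower (the same adjusted over the list alone). Heat shock stood at 3.10 (camera adjusted p = 1.21e-17, and adjusted p = 0.207 with an estimated correlation). HSFA2 rose from 1.21 ± 1.03 to 24.97 ± 7.61 FPKM (log2 fold change 3.61 ± 0.40, limma adjusted p = 3.29e-05).

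WRKY33 rose from 9.07 ± 5.33 to 122 ± 76.0 FPKM (log2 fold change 3.56 ± 0.49, limma adjusted p = 0.000177). The zinc finger factor gene ZAT12 rose from 8.26 ± 3.05 to 154 ± 50.2 FPKM (log2 fold change 4.07 ± 0.36, limma adjusted p = 5.24e-06). PAD3 rose from 0.892 ± 0.275 to 39.3 ± 17.56 FPKM (log2 fold change 4.34 ± 0.29, limma adjusted p = 4.75e-07). In pattern-triggered immunity 25 of 29 tested members were higher and 0 lower (27 and 0 adjusted over the list alone). Pattern-triggered immunity stood at 1.56 (camera adjusted p = 8.98e-17, and adjusted p = 0.207 with an estimated correlation). In camalexin and indolic compounds 9 of 16 tested members were higher and 0 lower (9 and 1 adjusted over the list alone). Camalexin and indolic compounds stood at 0.91 (camera adjusted p = 1.01e-05, and adjusted p = 0.207 with an estimated correlation). In ethylene synthesis and response 16 of 20 tested members were higher and 0 lower (18 and 0 adjusted over the list alone). Ethylene synthesis and response stood at 1.18 (camera adjusted p = 7.87e-11, and adjusted p = 0.207 with an estimated correlation). ERF5, an ethylene response factor gene, rose by 3.12 ± 0.34 (limma adjusted p = 3.16e-05). In salicylic acid and systemic resistance 7 of 18 tested members were higher and 1 lower (8 and 1 adjusted over the list alone). Salicylic acid and systemic resistance stood at 0.21 (camera adjusted p = 0.0235, and adjusted p = 0.482 with an estimated correlation), and fry did not call it (adjusted p = 0.0675). CBP60G, a regulator of salicylic acid synthesis, rose from 2.90 ± 0.580 to 13.6 ± 5.74 FPKM (log2 fold change 1.84 ± 0.27, limma adjusted p = 0.000327).

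Calcium sensing, hypoxia, low energy, auxin and clock lists were also called higher. In calcium sensing 8 of 12 tested members were higher and 0 lower (9 and 0 adjusted over the list alone). Calcium sensing stood at 1.38 (camera adjusted p = 1.19e-06, and adjusted p = 0.226 with an estimated correlation). TCH4 rose from 7.53 ± 2.40 to 93.7 ± 39.8 FPKM (log2 fold change 3.42 ± 0.38, limma adjusted p = 3.31e-05). In low energy 14 of 17 tested members were higher and 1 lower (15 and 1 adjusted over the list alone). Low energy stood at 1.19 (camera adjusted p = 3.75e-08, and adjusted p = 0.207 with an estimated correlation). In hypoxia 7 of 10 tested members were higher and 0 lower (the same adjusted over the list alone). Hypoxia stood at 0.93 (camera adjusted p = 0.000102, and adjusted p = 0.226 with an estimated correlation). PGB1, a haemoglobin gene, rose from 0.992 ± 0.161 to 9.69 ± 0.889 FPKM (log2 fold change 2.42 ± 0.21, limma adjusted p = 4.45e-06). In auxin response 5 of 14 tested members were higher and 0 lower (7 and 0 adjusted over the list alone). Auxin response stood at 0.44 (camera adjusted p = 0.00625, and adjusted p = 0.226 with an estimated correlation). IAA2 rose from 82.1 ± 7.62 to 169 ± 13.2 FPKM (log2 fold change 1.04 ± 0.15, limma adjusted p = 0.000335). In the clock list 3 of 12 tested members were higher and 0 lower (the same adjusted over the list alone). The clock list stood at 0.32 (camera adjusted p = 0.0241, and adjusted p = 0.383 with an estimated correlation). Of these calls 2, PRR9 and RVE8, did not hold without single libraries (limma adjusted p up to 0.148 without DC3000 replicate 3 and 0.0682 without valinomycin+DC3000 replicate 2).

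The lists of jasmonate, abscisic acid, glucosinolates, flavonoids, photosynthesis and cell division were called lower with both treatments than with DC3000 alone, jasmonate through 9 of its 26 members. VSP2 fell from 416 ± 165 to 111 ± 26.1 FPKM (log2 fold change -1.84 ± 0.31, limma adjusted p = 0.000808). AOC2 fell from 551 ± 129 to 276 ± 22.02 FPKM (log2 fold change -0.97 ± 0.18, limma adjusted p = 0.00149). In jasmonate synthesis and response 9 of 26 tested members were lower and 0 higher (12 and 1 adjusted over the list alone). Jasmonate synthesis and response stood at -0.36 (camera adjusted p = 0.00712, and adjusted p = 0.602 with an estimated correlation), and fry did not call it (adjusted p = 0.161). COR15A (AT2G42540; chromosome 2, 17710441 to 17712330, minus strand), which encodes a chloroplast protein of freezing tolerance, fell from 973 ± 402 to 134 ± 11.4 FPKM (log2 fold change -2.75 ± 0.31, limma adjusted p = 4.11e-05). KIN1, induced by cold and abscisic acid, fell from 124 ± 41.9 to 14.3 ± 1.03 FPKM (log2 fold change -2.97 ± 0.49, limma adjusted p = 0.000653). In abscisic acid and water deficit 14 of 26 tested members were lower and 3 higher (the same adjusted over the list alone). Abscisic acid and water deficit stood at -0.77 (camera adjusted p = 0.000798, and adjusted p = 0.451 with an estimated correlation), and fry did not call it (adjusted p = 0.0608). CER1, of cuticular wax synthesis, fell by 2.56 and LTP3, a lipid transfer protein gene, fell by 3.01 on the log2 scale (limma adjusted p = 5.77e-06 and 0.000301). In aliphatic glucosinolates 7 of 14 tested members were lower and 0 higher (8 and 0 adjusted over the list alone). Aliphatic glucosinolates stood at -0.69 (camera adjusted p = 0.000102, and adjusted p = 0.351 with an estimated correlation). BAT5, a plastid transporter gene of this pathway, fell from 11.4 ± 4.003 to 3.76 ± 0.740 FPKM (log2 fold change -1.34 ± 0.23, limma adjusted p = 0.00084). In flavonoids and anthocyanins 5 of 8 tested members were lower and 0 higher (7 and 0 adjusted over the list alone). Flavonoids and anthocyanins stood at -0.67 (camera adjusted p = 0.000562, and adjusted p = 0.226 with an estimated correlation). CHS, the first enzyme of the pathway, fell from 29.1 ± 15.8 to 6.07 ± 2.80 FPKM (log2 fold change -2.01 ± 0.38, limma adjusted p = 0.0018). In photosynthesis 39 of 48 tested members were lower and 0 higher (44 and 0 adjusted over the list alone). Photosynthesis stood at -0.51 (camera adjusted p = 1.05e-14, and adjusted p = 0.207 with an estimated correlation). In cell division 9 of 14 tested members were lower and 0 higher (11 and 0 adjusted over the list alone). Cell division stood at -0.68 (camera adjusted p = 2.85e-05, and adjusted p = 0.258 with an estimated correlation). Markers of other cell types were 1 lower and 1 higher of 6 for guard cells (1 and 1 adjusted over the list alone) and 2 lower and 0 higher of 5 for roots (3 and 0 adjusted over the list alone). They were 2 lower and 0 higher of 9 for phloem and xylem (2 and 0 adjusted over the list alone) and 4 lower and 1 higher of 6 for meristem and epidermis (4 and 1 adjusted over the list alone). None of these 4 lists was called (camera adjusted p = 0.857, 0.0531, 0.656 and 0.243).

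In total 4987 genes were called, 2551 higher and 2436 lower, and 1517 changed at least 2-fold, 1159 higher and 358 lower. Camera called 18 lists, 12 higher and 6 lower, and 0 with an estimated correlation, the lowest adjusted p being 0.207, and fry called 16. The count of genes was 3276 without DC3000 replicate 1, 3323 without DC3000 replicate 2 and 2914 without replicate 2 of both treatments. In potassium transport 5 of 32 tested members were higher and 4 lower (the same adjusted over the list alone). Potassium transport was not called (camera adjusted p = 0.656, and adjusted p = 0.919 with an estimated correlation). KAT1, a potassium channel gene of guard cells, stood at 7.74 ± 2.83 with DC3000 and 2.76 ± 0.123 FPKM with both (log2 fold change -1.16 ± 0.26, limma adjusted p = 0.00489).

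Both treatments against valinomycin alone asks what the bacterium changed in seedlings that also received valinomycin. Genes of the jasmonate response were among the largest rises. NATA1 rose from 0.449 ± 0.393 to 138 ± 3.93 FPKM (log2 fold change 6.62 ± 0.20, limma adjusted p = 7.01e-11). CLH1, which encodes a chlorophyllase, rose from 17.36 ± 2.08 to 512 ± 104 FPKM (log2 fold change 4.79 ± 0.20, limma adjusted p = 6.27e-09). LOX2, a lipoxygenase of jasmonate synthesis, rose from 73.1 ± 15.2 to 1036 ± 139 FPKM (log2 fold change 3.82 ± 0.23, limma adjusted p = 1.07e-07). In jasmonate synthesis and response 25 of 26 tested members were higher and 0 lower (the same adjusted over the list alone). Jasmonate synthesis and response stood at 2.55 relative to all genes, whose median was -0.12 (camera adjusted p = 2.04e-45, and adjusted p = 0.104 with an estimated correlation). In aliphatic glucosinolates 8 of 14 tested members were higher and 0 lower (11 and 0 adjusted over the list alone). Aliphatic glucosinolates stood at 1.17 (camera adjusted p = 1.68e-09, and adjusted p = 0.364 with an estimated correlation). MAM1 rose from 20.7 ± 10.6 to 61.5 ± 8.12 FPKM (log2 fold change 1.62 ± 0.27, limma adjusted p = 0.00128). In camalexin and indolic compounds 8 of 16 tested members were higher and 0 lower (9 and 1 adjusted over the list alone). Camalexin and indolic compounds stood at 1.103 (camera adjusted p = 3.52e-07, and adjusted p = 0.303 with an estimated correlation). CYP79B3, which converts tryptophan towards indolic compounds, rose from 25.1 ± 2.18 to 126 ± 20.4 FPKM (log2 fold change 2.27 ± 0.24, limma adjusted p = 2.44e-05). In low energy 3 of 17 tested members were higher and 0 lower (4 and 0 adjusted over the list alone). Low energy stood at 0.46 (camera adjusted p = 0.00127, and adjusted p = 0.66 with an estimated correlation), and fry did not call it (adjusted p = 0.349). In ethylene 4 of 20 tested members were higher and 0 lower (the same adjusted over the list alone). Ethylene stood at 0.29 (camera adjusted p = 0.00537, and adjusted p = 0.691 with an estimated correlation; camera adjusted p = 0.0549 after rescaling), and fry did not call it (adjusted p = 0.349). In potassium transport 4 of 32 tested members were higher and 1 lower (4 and 2 adjusted over the list alone). Potassium transport stood at 0.13 (camera adjusted p = 0.048, and adjusted p = 0.98 with an estimated correlation). With a replicate block it was not called (camera adjusted p = 0.0539), nor by fry (adjusted p = 0.816). TPK3 rose from 4.33 ± 0.621 to 10.0 ± 1.75 FPKM (log2 fold change 1.04 ± 0.18, limma adjusted p = 0.00164). NHX1, a vacuolar exchanger gene of sodium and potassium, rose from 11.4 ± 1.84 to 25.9 ± 2.21 FPKM (log2 fold change 1.12 ± 0.24, limma adjusted p = 0.00694).

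The lists of photosynthesis, endoplasmic reticulum stress, epidermis and auxin were called lower by camera, while immunity and mitochondrial lists were not called. In pattern-triggered immunity 2 of 29 tested members were lower and 0 higher (the same adjusted over the list alone). Pattern-triggered immunity was not called (camera adjusted p = 0.532, and adjusted p = 0.98 with an estimated correlation). FLS2, the flagellin receptor gene, fell from 15.5 ± 6.84 to 4.65 ± 0.0972 FPKM (log2 fold change -1.46 ± 0.24, limma adjusted p = 0.00136). In mitochondrial stress 0 of 18 tested members were higher and 0 lower (the same adjusted over the list alone). Mitochondrial stress was not called (camera adjusted p = 0.852, and adjusted p = 0.98 with an estimated correlation). AOX1A stood at 249.8 ± 125 and 246 ± 71.0 FPKM (limma adjusted p = 0.88). In photosynthesis 37 of 48 tested members were lower and 0 higher (46 and 0 adjusted over the list alone, and 24 and 0 after rescaling). Photosynthesis stood at -0.50 (camera adjusted p = 1.94e-17, and adjusted p = 0.34 with an estimated correlation). RBCS1B, a Rubisco small subunit gene, fell from 748 ± 149.6 to 322 ± 32.8 FPKM (log2 fold change -1.20 ± 0.15, limma adjusted p = 9.87e-05). In endoplasmic reticulum stress 5 of 20 tested members were lower and 0 higher (10 and 0 adjusted over the list alone, and 7 and 0 after rescaling). Endoplasmic reticulum stress stood at -0.36 (camera adjusted p = 0.00499, and adjusted p = 0.66 with an estimated correlation). The folding protein gene CNX1 fell from 54.0 ± 15.9 to 27.6 ± 3.57 FPKM (log2 fold change -0.91 ± 0.19, limma adjusted p = 0.0068). In meristem and epidermis markers 3 of 6 tested members were lower and 0 higher (6 and 0 adjusted over the list alone). Meristem and epidermis markers stood at -0.36 (camera adjusted p = 0.00347, and adjusted p = 0.539 with an estimated correlation). PDF1, of the epidermis, fell from 97.9 ± 19.8 to 39.9 ± 6.17 FPKM (log2 fold change -1.27 ± 0.21, limma adjusted p = 0.00117). In auxin response 4 of 14 tested members were lower and 0 higher (5 and 0 adjusted over the list alone). Auxin response stood at -0.37 (camera adjusted p = 0.048, and adjusted p = 0.66 with an estimated correlation). The largest falls included LTP3 at -2.77 ± 0.44, the uncharacterized gene AT3G62695 at -2.15 ± 0.39 and the chloroplast locus ATCG00880 at -2.77 ± 0.54, from 1467 ± 796 to 248 ± 199.7 FPKM (limma adjusted p = 0.000984, 0.00239 and 0.00395).

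In total 2720 genes were called, 851 higher and 1869 lower, and 706 changed at least 2-fold, 438 higher and 268 lower. After rescaling 3428 were called, 1852 higher and 1576 lower, and with the nuclear scaling 1790 were higher and 1267 lower, so the excess of falls in this comparison is not kept under either. Camera called 10 lists, 6 higher and 4 lower, and 0 with an estimated correlation, the lowest adjusted p being 0.104, and fry called 8. The count of genes was 1807 without valinomycin replicate 2, and 1596, 1769 and 1691 without replicates 1, 2 and 3 of both treatments.

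Both treatments against mock asks what the treatments did together. AOX1A rose from 4.37 ± 0.722 to 246 ± 71.0 FPKM (log2 fold change 5.49 ± 0.32, limma adjusted p = 5.73e-09). VSP2 rose from 2.58 ± 0.526 to 111 ± 26.1 FPKM (log2 fold change 4.95 ± 0.31, limma adjusted p = 1.16e-08), to a lower level than with DC3000 alone. LHCB2.3 fell from 903 ± 51.6 to 79.3 ± 21.8 FPKM (log2 fold change -3.52 ± 0.20, limma adjusted p = 4.48e-09). In mitochondrial stress 16 of 18 tested members were higher and 1 lower (the same adjusted over the list alone). Mitochondrial stress stood at 3.298 (camera adjusted p = 3.28e-06, and adjusted p = 0.425 with an estimated correlation). In jasmonate 26 of 26 tested members were higher and 0 lower (the same adjusted over the list alone). Jasmonate stood at 4.13 (camera adjusted p = 8.21e-16, and adjusted p = 0.42 with an estimated correlation), relative to a median of 0.17 for all genes. In photosynthesis 44 of 48 tested members were lower and 0 higher (the same adjusted over the list alone). Photosynthesis stood at -1.25 (camera adjusted p = 7.16e-19, and adjusted p = 0.42 with an estimated correlation). In meristem and epidermis markers 3 of 6 tested members were lower and 0 higher (the same adjusted over the list alone). Meristem and epidermis markers stood at -0.71 (camera adjusted p = 0.0117, and adjusted p = 0.425 with an estimated correlation). In total 10884 genes were called, 6711 higher and 4173 lower, against 6003 higher and 5726 lower after rescaling, and 4774 changed at least 2-fold, 3028 higher and 1746 lower. Camera called 14 lists, 10 higher and 4 lower, and 0 with an estimated correlation, the lowest adjusted p being 0.42, and fry called 22.

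The valinomycin effect was measured both without and with DC3000, in separate libraries. Across genes its fold changes had a Pearson r of 0.609 and a Spearman rho of 0.507, and genes are not independent replicates. Of the genes called in both, 2011 were higher in each, against 981 from the product of the shares, 926 were lower in each, against 337, and 410 moved in opposite directions. AOX1A, UPOX, WRKY33, PAD3 and HSP17.6A were among those higher in each. The 2937 genes with shared direction became 1920 without replicate 2 of both treatments. Valinomycin and DC3000, against the same mock libraries, shared 6164 genes in direction, 4300 higher (2196 from the product of the shares) and 1864 lower (428), with 211 opposite, r = 0.649 and rho = 0.699. In 100 simulations of unchanged groups against the same mock libraries r averaged 0.499, which comparisons with a shared control give by construction. At most 1 gene was shared, since no gene was changed. The covariance averaged 0.0204 against 0.553 observed, so random spread of the mock libraries gave a small part of the observed covariance. A mock group that differs as a whole, as in the clock genes, was not simulated, and its share of the overlap is untested. The DC3000 effect without and with valinomycin had r = 0.625 and rho = 0.542, with 1817 genes shared in direction and 146 opposite.

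**Figure D4:**
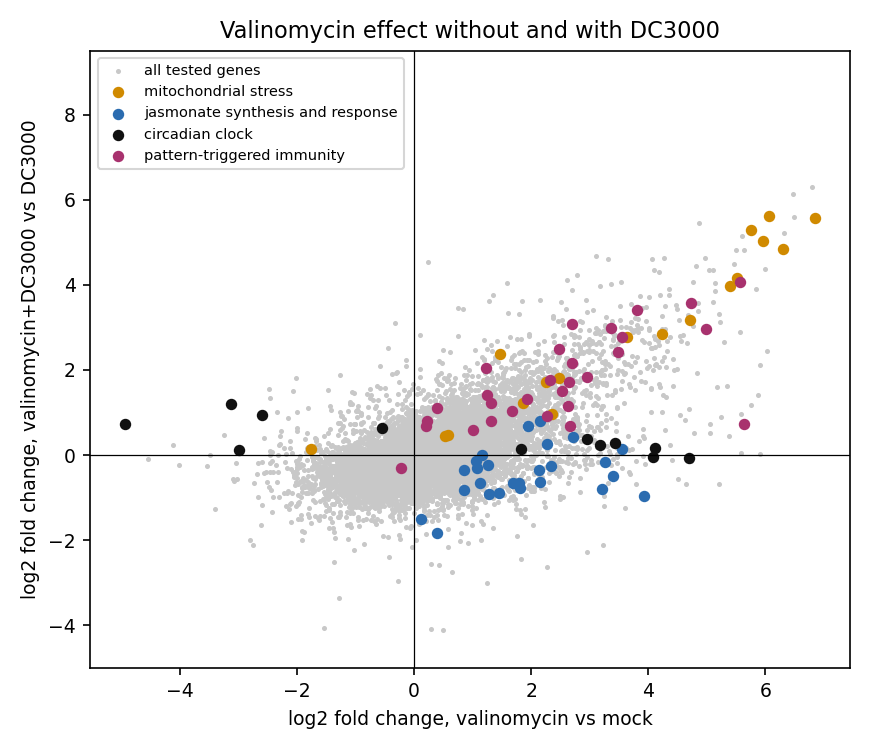
Log2 fold change of valinomycin against mock (x) and of both treatments against DC3000 (y) for each of the 18048 tested genes, with 4 gene lists coloured. Most mitochondrial stress and immunity genes lie in the upper right, jasmonate genes mostly at or below 0 on the y axis, and most clock genes far from 0 on the x axis, with CCA1 also at 1.19 and RVE8 at 0.95 on the y axis and PRR9 at -0.55 and 0.64 on the x and y axes.

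The interaction asks for which genes the valinomycin effect differed with and without DC3000. LHY had the largest positive value, 5.68 ± 0.54 (limma adjusted p = 6.46e-06), followed by COL2 at 4.46 ± 0.22 and BMY3 at 4.34 ± 0.33 (limma adjusted p = 1.16e-08 and 9.11e-07). AT4G16240, CCL and AT2G43620 had the largest negative values, -5.90 ± 0.37, -5.88 ± 0.26 and -5.53 ± 0.27 (limma adjusted p = 1.22e-07, 1.14e-08 and 1.16e-08). CCL stood at 24.2 ± 7.19 FPKM in mock, 1479 ± 158 with valinomycin, 1118 ± 46.2 with DC3000 and 1147 ± 93.3 with both. All 12 clock genes were called. In jasmonate 24 of 26 tested members were lower and 0 higher (26 and 0 adjusted over the list alone). Jasmonate stood at -1.97 relative to all genes, whose median was -0.29 (camera adjusted p = 2.49e-13, and adjusted p = 0.821 with an estimated correlation). In abscisic acid 15 of 26 tested members were lower and 1 higher (16 and 1 adjusted over the list alone). Abscisic acid stood at -1.50 (camera adjusted p = 0.00101, and adjusted p = 0.93 with an estimated correlation). In auxin response 6 of 14 tested members were higher and 0 lower (7 and 1 adjusted over the list alone). Auxin response stood at 1.01 (camera adjusted p = 0.000695, and adjusted p = 0.821 with an estimated correlation). In phenylpropanoids and lignin 3 of 15 tested members were higher and 1 lower (the same adjusted over the list alone). Phenylpropanoids and lignin stood at 0.41 (camera adjusted p = 0.00262, and adjusted p = 0.93 with an estimated correlation). In flavonoids and anthocyanins 2 of 8 tested members were higher and 0 lower (3 and 2 adjusted over the list alone). Flavonoids and anthocyanins stood at 0.72 (camera adjusted p = 0.03, and adjusted p = 0.93 with an estimated correlation; camera adjusted p = 0.124 after rescaling). In heat shock 3 of 19 tested members were higher and 3 lower (4 and 3 adjusted over the list alone). Heat shock stood at 0.36 (camera adjusted p = 0.03, and adjusted p = 0.93 with an estimated correlation; camera adjusted p = 0.235 after rescaling). These 3 lists were called higher by camera, with few members called, and fry did not call them (adjusted p = 0.282, 0.231 and 0.734). In total 4449 genes were called, 947 higher and 3502 lower, against 2487 and 2186 after rescaling. Camera called 6 lists, 4 higher and 2 lower, and 0 with an estimated correlation, the lowest adjusted p being 0.821, and fry called 7.

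Of the 150 list results, 71 were called by camera, and in 21 the median, the mean and the test differed in sign, of which 0 were called. Among the genes named with a fold change, ASA1, AT3G62695, BMY3, CHS, COL2, COR15B, F3H, FLS2, FRK1, IAA3, JAZ10, KNOLLE, LHCB2.3, RCA, WRKY33 and WRKY40 share an exon region with a gene on the opposite strand, and since the use of strand in counting is not given their values are uncertain to that extent.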

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

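The tests of explanations in this part, the counts over other splits of the libraries among them, were chosen after the results were seen, while the comparisons themselves were fixed earlier. The valinomycin effect with DC3000 differed from that without DC3000 in 4449 genes by the limma interaction and in 6 gene lists by camera with the preset correlation, but in 0 lists with an estimated correlation (lowest adjusted p = 0.821). A difference between groups of this kind is why these results are given here. Single genes with the largest difference on the log2 scale were LHY at 5.68, COL2 at 4.457, BMY3 at 4.345, AT2G43620 at -5.528, CCL at -5.879 and AT4G16240 at -5.898. Of 100 splits of the 12 libraries, 3 gave as many genes, the real one included, and the highest other gave 7547. These splits mix libraries across treatments that differ in many genes, so they bear on whether the groups differ at all and leave open whether chance gives an interaction of this size. What gave the split with 7547 genes its count was not tested. For the count of lists 87 of 100 splits gave 6 or more, with up to 17, and the same limit holds.

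All 12 clock genes differed between mock and each treated group, and the interaction of LHY, COL2, BMY3 and CCL goes with values that lie far from mock in all 3 treated groups. The combined effect over the sum of the single effects had a median of 0.504 (range 0.392 to 0.524) over the clock genes, where 1 stands for effects that add up and 0.5 for treated groups at like levels. The authors' scaling as the cause is argued against, since all 12 clock genes stayed called in the same direction in the 3 groups after rescaling. In valinomycin replicate 3 the clock genes had moved by a median of 1.048 of the mean of replicates 1 and 2 (quartiles 0.989 to 1.392), while its mitochondrial stress genes had moved by 0.686 (0.63 to 0.74), but a single library decides nothing. Mock seedlings sampled at another clock phase, and a clock response that both treatments set off alike, cannot be told apart, because every mock library stands on the same side.

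Valinomycin replicate 3 lay nearer to mock than replicates 1 and 2. RNA of mock seedlings in that library is argued against: 42 genes far lower than mock imply a median share of mock RNA of 1.15% (quartiles -3.19 to 3.77), while 359 genes far higher imply 61.0% (45.1 to 69.9). RNA of DC3000 seedlings is argued against too, with an implied share of 0.25% (quartiles -4.43 to 2.06) over 95 genes. The authors' scaling is argued against, as the slope of this library on the combined effect was 0.601 after rescaling, against 0.840 and 0.799 for the others. A weaker or slower valinomycin response in that library is untested and may remain, and without it 9307 genes were called in valinomycin against mock.

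Jasmonate and abscisic acid genes were lower with both treatments than with DC3000 alone in 23 of 52 tested members. The authors' scaling is argued against, since 22 members were lower after rescaling. In DC3000 replicate 3 VSP2 stood at 231 FPKM, against 469 and 547 in replicates 1 and 2. JAZ10 stood at 139 FPKM, against 274 and 284, and COR15A at 510 FPKM, against 1175.5 and 1234.8. Ribosomal RNA loci made up 21.4% of that library, against 13.2% and 13.3% in replicates 1 and 2. The lists were not run without it. Among 318 other genes higher with DC3000 and close to mock with valinomycin alone, the DC3000 effect with valinomycin was a median 0.543 of that without (quartiles 0.31 to 0.72). For the 26 jasmonate genes the median was 0.53 (quartiles 0.389 to 0.637). Valinomycin alone raised 24 of these, and their ratio takes in that rise, so the 2 ratios are not alike. The median log2 fold change of the jasmonate list against mock was 1.795 with valinomycin, 4.654 with DC3000 and 4.302 with both. The 318 genes were chosen for a large DC3000 effect without valinomycin, which by itself lowers their ratio, by an amount not tested. With no measure of bacteria, a weaker exposure to DC3000 in the combined treatment and a weaker plant response cannot be told apart for either list. The DC3000 effect without valinomycin also takes in any difference of mock from all treated groups. All 12 clock genes were called in that effect, against 2 in the DC3000 effect with valinomycin. COL2, BMY3 and CCL, outside the clock list, also lie far from mock in every treated group. Whether this difference reaches jasmonate or abscisic acid genes was not tested.

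For the other comparisons 3 libraries against 3 allow 10 splits, too few for a share under 0.05. Counting the real split, 1 of 10 gave as many genes in each: 9436 for valinomycin against mock, 8803 for DC3000 against mock, 10884 for both against mock and 4987 for both against DC3000, with 0 as the highest other in all 4, and 2720 for both against valinomycin, with 334 as the highest other. For lists the numbers of splits with a result as large were 3 (14 lists, highest other 16), 7 (9 and 13), 5 (14 and 14), 2 (18 and 19) and 7 (10 and 16) in the same order.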

How the results depend on the processing

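The nuclear scaling in this part was chosen after seeing the data, and the other settings were fixed before. With a minimum mean of 10 FPKM the counts of genes were 4908 for valinomycin against mock, 4885 for DC3000 against mock, 5625 for both against mock, 2785 for both against DC3000, 1620 for both against valinomycin and 2720 for the interaction, and 1685 genes shared direction in the valinomycin effect without and with DC3000 and 3582 in the responses to valinomycin and to DC3000, since fewer genes were tested. The counts of genes called in the 6 comparisons stayed within 1.5 times the reported ones with a pseudocount of 0.1 or 5, without a filter, after median-of-ratios rescaling, with only the 2 groups compared in the fit (not run for the interaction), and with a replicate block, which gave 9704, 9115, 11078, 5338, 2928 and 4954 genes in the same order of comparisons. The 2 counts of shared genes were run with a pseudocount of 5, rescaling and the replicate block as well, and stayed within the same bound. Scaling nuclear genes to 1 total gave 9584, 9501, 11605, 5840, 3057 and 4447. With median-of-ratios rescaling the share of called genes that were higher went from 73.6% to 49.7%, 64.8% to 48.7%, 61.7% to 51.2%, 51.2% to 52.0%, 31.3% to 54.0% and 21.3% to 53.2% in that order, as this rescaling by construction sets the median change near 0. With the nuclear scaling the shares were 66.5%, 63.0%, 63.5%, 59.6%, 58.6% and 35.6%. The excess of rises against mock and of falls in the interaction thus stayed under that scaling, while in both against valinomycin an excess of falls (851 higher and 1869 lower) became one of rises (1790 and 1267). With an estimated correlation camera called 0 lists in each of the 6 comparisons, against 1, 2, 2, 4, 3 and 1 at an unadjusted p under 0.05. Fry called 15 lists in DC3000 against mock and 22 in both against mock, where the cause was not tested, and 18, 16, 8 and 7 in the others.

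Leaving out each library gave 7510 to 9372 genes for valinomycin against mock, 7243 to 8639 for DC3000 against mock, 9686 to 10533 for both against mock, 2914 to 4493 for both against DC3000, 1596 to 2804 for both against valinomycin and 3061 to 4872 for the interaction. In both against DC3000 the count was 3276 without DC3000 replicate 1, 3323 without DC3000 replicate 2 and 2914 without replicate 2 of both treatments. In both against valinomycin it was 1807 without valinomycin replicate 2 and 1596, 1769 and 1691 without replicates 1, 2 and 3 of both treatments. The genes that shared direction in the valinomycin effect numbered 1920 to 3442, with 1920 without replicate 2 of both treatments, and those shared between valinomycin and DC3000 numbered 5143 to 6182.

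Of the named genes' results, 605 kept their direction and side of the threshold with a pseudocount of 0.1, 584 with 5, 606 without a filter, 580 after rescaling, 591 with the nuclear scaling and 606 with a replicate block. After rescaling 31 were no longer called and 4 became called. Leaving out single libraries kept 3876, ended 371 calls and added 18. No result reversed. Of the 150 list results 142 were the same after rescaling, 3 were no longer called and 5 became called. These 5 were potassium transport and xenobiotic detoxification in DC3000 against mock (camera adjusted p = 0.0275 and 0.0222), cell division in both against valinomycin (0.0455), and xenobiotic detoxification and photosynthesis in the interaction (0.017 and 0.0155). With a replicate block 148 were the same, phenylpropanoids and lignin became called in valinomycin against mock (camera adjusted p = 0.046) and potassium transport in both against valinomycin was no longer called (0.0539). A count model (DESeq2 or edgeR on counts) was not run, since the values are FPKM. Depth is known in 6 libraries, where 1 FPKM is 20.2 to 22.6 fragments on a median transcript, so genes near that level rest on few fragments.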

Other observations

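Families of genes outside the 25 lists were chosen after the data were seen and tested with camera against all other genes. Arabinogalactan protein genes were lower in 20 and higher in 0 of 32 tested members with both treatments than with valinomycin alone (median log2 fold change -0.78, and -0.67 after rescaling; camera adjusted p = 2.22e-09, and adjusted p = 0.16 with an estimated correlation). Histone genes were lower in 26 and higher in 0 of 43 in the same comparison (median -0.62, and -0.50 after rescaling; camera adjusted p = 2.23e-10, and adjusted p = 0.572 with an estimated correlation). MATE efflux carrier genes were higher in 12 and lower in 2 of 32 (median 0.28, and 0.37 after rescaling; camera adjusted p = 1.19e-06, and adjusted p = 0.678 with an estimated correlation). Against mock, arabinogalactan protein genes were lower in 21 and higher in 2 with valinomycin, and lower in 25 and higher in 1 with DC3000. Histone genes were lower in 20 and higher in 10 with valinomycin against mock, and lower in 30 and higher in 3 with DC3000 against mock.

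Aquaporin genes were lower in 14 and higher in 0 of 20 with both treatments than with DC3000 alone (median -0.63, and -0.60 after rescaling; camera adjusted p = 6.86e-06, and adjusted p = 0.55 with an estimated correlation). WRKY factor genes were higher with valinomycin than in mock in 25 of 31 and lower in 0 (median 1.19, and 1.03 after rescaling; camera adjusted p = 3.79e-06, and adjusted p = 0.489 with an estimated correlation). Ribosomal protein genes were lower in 149 and higher in 43 of 314 with valinomycin (median -0.34, and -0.64 after rescaling; camera adjusted p = 9.89e-15, and adjusted p = 0.489 with an estimated correlation) and lower in 146 and higher in 36 with DC3000 (median -0.35, and -0.56 after rescaling; camera adjusted p = 1.01e-09, and adjusted p = 0.699 with an estimated correlation), each against mock. Replicates of a group had Spearman correlations from 0.942 (valinomycin replicates 1 and 3) to 0.988.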
